A study of Mus musculus with 33 samples.

How the data were processed

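Poly-A RNA of 33 mouse libraries was sequenced: MEFs, and cells of days 3, 6, 9 and 12 of reprogramming and of the iPS stage, each sorted into SSEA1neg and SSEA1pos fractions, with 3 libraries in each of 11 groups. Per the labels' protocols, MEFs grew in MEF medium and reprogramming ran in embryonic stem cell medium with doxycycline and ascorbic acid, cells were sorted after trypsin digestion, and libraries were made with a kit that marks strand. The values used are raw counts of reads per Ensembl gene, deposited by the authors as 1 file per library. The submitters' processing notes name STAR 2.3.0, Picard 1.100, HTSeq 0.6.0 and the genome build mm9 without their roles, and the annotation release is not given in the sources used here. Only the names of the deposited files speak of counting without strand, so reads of a gene and of its antisense partner cannot be told apart, and multi-copy RNAs such as Rn7sk and n-R5-8s1 are uncertain because reads with several alignments were not counted in genes.

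Groups and replicate numbers came from the labels. Nothing in them says that replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which could be technical. All files held 37583 gene IDs, of which 32860 had a symbol in the reference annotation and 4723 had none; 3 symbols were shared by several IDs. That annotation (GENCODE M21) belongs to another build than mm9, so it gave only names, chromosome membership, transcript GC content and length, and no coordinates are printed. Lines that name no gene stayed out of totals and tests. Reads assigned to no annotated gene made up 4.42 to 15.51% and ambiguous reads 2.41 to 3.15% of uniquely aligned reads. Reads with several alignments made up 14.95 to 27.24% of all reads. Reads assigned to no gene need not lie outside genes, and where they fell was not tested.

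Totals in genes ran from 8.93 to 41.69 M (median 23.15 M), with 16492 to 21246 genes with a read. A gene with 0 reads is compatible with up to 3 counts, which is 0.336 CPM in the shallowest and 0.072 CPM in the deepest library. Such floors cover counting error only, since reads without molecular identifiers are not independent molecules. The 20 most abundant genes took 17.63 ± 2.85% of the counts in MEFs and 6.71 to 8.9% in the other groups on average.

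Differences were tested with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, robust) on the deposited counts, with TMM normalisation and the filterByExpr filter, in one model of all 33 libraries with a mean per group and 22 residual degrees of freedom. Of all genes 17326 were tested. A gene was called where the Benjamini-Hochberg adjusted p was under 0.05 and the change at least 2-fold. Standard errors are approximate, being the log2 fold change divided by the square root of F. Comparisons were SSEA1pos against SSEA1neg at each of the 5 stages, each fraction of each stage against MEFs, successive SSEA1pos stages, and the interaction of the sort with day (day 12 against day 3). TMM left the median log2 change of all tested genes at up to 0.261 in comparisons with MEFs, and changes are relative to that scaling. Levels are TMM-normalised CPM. Principal components and correlations used log2 CPM with a prior count of 2, and mean list levels used log2(CPM + 1).

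Gene lists (30 in number) were tested with limma's camera on voom values with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Counts of list members are those of the test over all 17326 genes, and the count adjusted over the list alone is given where it differed. Genes were named by a rule: for each comparison the 6 largest increases and 6 largest decreases among called genes with a mean of at least 10 CPM in the higher group and values that do not overlap between the groups (chance gives this in 10% of genes for 3 against 3), leaving out predicted genes, RIKEN clones and IDs with no symbol. Of the genes so named, 1 is not reported here. Up to 4 members of each list with the smallest p were added, along with the reprogramming factor genes and Fut9, Fut4, Thy1, Cdh1, Epcam, Nanog, Esrrb, Dppa5a, Zfp42, Utf1, Lin28a, Col1a1, Nt5e, Itga4 and Tfap2c. The groups, tests, lists, naming rule and the settings to be compared, except those named as added, were fixed before the data were examined.

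Whether equal replicate numbers pair libraries was read from the data alone, since the labels do not say what a number shares. Deviations from the group means of same-numbered libraries correlated above 0.1 in each pair, before rounding, for the sort at days 3 (0.35 to 0.47), 6 (0.3 to 0.56), 9 (0.18 to 0.31) and 12 (0.18 to 0.24), for SSEA1pos cells of days 3 (0.15 to 0.23), 6 (0.11 to 0.14) and 12 (0.16 to 0.2) against MEFs, and for the steps to day 6 (0.39 to 0.56), day 9 (0.39 to 0.63) and day 12 (0.1 to 0.31). This was decided before the fits with and without a replicate block were compared.

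Alternatives were DESeq2 size factors, no filter on low counts (all genes with a read), DESeq2's Wald test, a replicate block, only the libraries of the groups compared, each library left out in turn, and all libraries thinned to the smallest total. Removing each library's trend on transcript GC content, alone or with length or with the replicate block, was added after seeing the data. That trend was a lowess curve (span 0.3) over 11658 genes with a mean log2 CPM of at least 1, and 96.3% of tested genes had a GC value. X-linked and autosomal genes were compared at a mean of at least 5 CPM. The file names of SSEA1neg libraries are written differently from the others, which could mark a batch; it holds 1 fraction only, so such a batch and the sort cannot be told apart.

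The statistics were tested on simulated counts for the day 12 sort comparison, with 100 genes changed at each fold size. Of 17071 genes, edgeR recovered 61% of 3-fold and 93% of 8-fold changes and called 3 of 16841 unchanged genes; with the replicate block it recovered 61% and 92% and called 5. DESeq2 recovered 73% and 95% of 17326 genes' changes and called 17 of 17096 unchanged ones. With a GC trend put in (17078 genes), 61% and 90% were recovered without and 63% and 93% with its removal. Of 16848 unchanged genes, 3 were called without and 4 with its removal. Mean slopes of log2 CPM per 10 GC points were -0.03 and 0.18 in day 12 SSEA1neg and SSEA1pos libraries. At day 3 they were -0.43 and -0.02. False calls from the wider gap at day 3 were not simulated. For a list of 30 genes shifted 2-fold camera's p-value was 1e-32, and for an unshifted list it was 0.71. Simulated genes varied independently of each other, so this does not test whether the preset correlation of 0.01 is large enough. The work used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.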

Results

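Poly-A selected RNA was sequenced from mouse embryonic fibroblasts (MEFs), from cells 3, 6, 9 and 12 days into reprogramming, and from cells at the induced pluripotent stem (iPS) cell stage. At each stage after MEFs the cells had been sorted by flow cytometry on SSEA1, a carbohydrate antigen of mouse pluripotent cells, into a negative (SSEA1neg) and a positive (SSEA1pos) fraction. The 11 groups held 3 libraries each, 33 in all. Reads counted in genes ranged from 8.93 M (MEF replicate 3) to 41.69 M (day 3 SSEA1neg replicate 3) per library, with a median of 23.15 M. By group, totals ran from 8.93 to 23.01 M in MEFs, and from 26.71 to 41.69, 23.87 to 32.59, 12.62 to 29.46, 23.15 to 28.36 and 17.17 to 27.33 M in SSEA1neg cells of days 3, 6, 9, 12 and the iPS stage. In SSEA1pos cells the same stages had 15.89 to 32.8, 18.04 to 22.75, 19.62 to 24.87, 18.78 to 26.76 and 16.7 to 18.11 M. Changes are log2 fold change ± standard error. Levels are CPM, read counts scaled to a common normalised library total, mean ± SD with n = 3 per group. A gene is said to have risen or fallen when its adjusted p was under 0.05 and its change at least 2-fold. Libraries of the same group correlated at r = 0.905 to 0.991 across genes. Every such pair differed by more than counting noise (chi-square per degree of freedom of at least 13.1).

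The first principal component, 39.5% of the variance, set MEFs (-118.3 to -108.7) apart from the iPS-stage SSEA1pos libraries (184 to 212.3), with the SSEA1pos libraries of days 3 to 12 in order of day between them. SSEA1neg libraries of days 3 to 12 lay at -88 to -33.1 on this component. The second component (21.1%) was highest in the day 3 SSEA1pos libraries (99.1 to 119.6) and lowest in the iPS-stage SSEA1neg libraries (-137.6 to -100.8). Replicate 3 of the iPS-stage SSEA1neg group lay at 42.9 on the first component, against -5.6 and -33.8 for replicates 1 and 2.

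**Figure D1:**
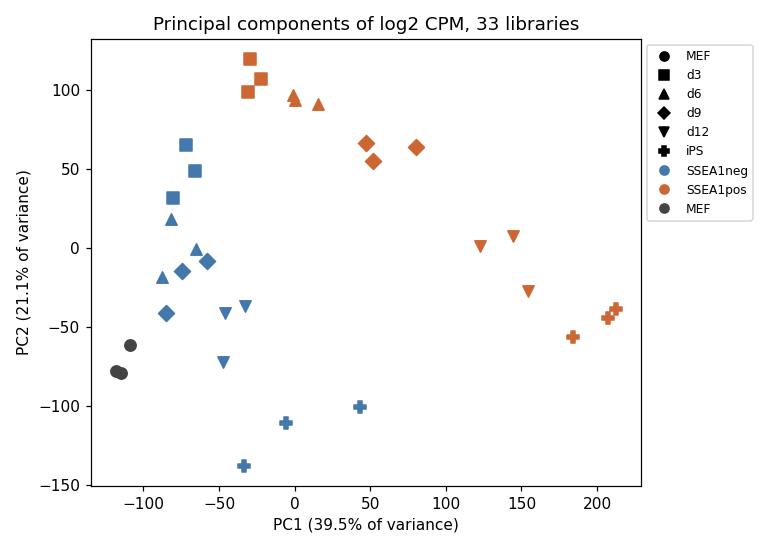
Each point is 1 of the 33 libraries, placed by its first and second principal component scores of log2 CPM (39.5% and 21.1% of the variance); shape gives the stage and colour the fraction. SSEA1pos libraries of days 3 to 12 fall in order of day along the first component, while SSEA1neg libraries of days 3 to 12 stay between -88 and -33.1.

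At day 3, SSEA1pos cells had lost most of the MEF matrix programme and carried the reprogramming factors. Col1a1 (ENSMUSG00000001506), the main fibrillar collagen chain, went from 37600 ± 1300 CPM in MEFs to 49 ± 14 (log2 fold change -9.59 ± 1.16, adjusted p = 3.5e-07). Postn, another matrix protein, changed by -12.26 ± 1.1. Of the fibroblast and mesenchymal list, 31 of 34 measured members fell and 0 rose (camera, adjusted p = 1.3e-17, adjusted p = 0.038 with an estimated correlation). Of the TGF-beta response list, 19 of 20 fell and 0 rose, with Pmepa1 at -4.9 ± 0.39 (adjusted p = 7.8e-13, adjusted p = 0.038 with an estimated correlation). All 4 reprogramming factor genes rose (adjusted p = 0.001, adjusted p = 0.3 with an estimated correlation). Sox2 went to 344 ± 25 CPM (6.37 ± 0.86), Pou5f1 to 226 ± 3.4 CPM (6 ± 0.82), and Klf4 and Myc changed by 3.04 ± 0.39 and 3.15 ± 0.42. Reads from an introduced copy and the cell's own gene cannot be told apart. Cell-cycle genes rose together, with 20 of 20 rose and 0 fell in the S phase list (adjusted p = 1.8e-08, adjusted p = 0.43 with an estimated correlation). Mcm7, a replication helicase gene, rose by 2.27 ± 0.33. In the G2 and M phase list 20 of 20 rose and 0 fell (adjusted p = 4.4e-10, adjusted p = 0.43 with an estimated correlation). MEF replicate 1 stood apart from replicates 2 and 3 in both lists, with a mean log2(CPM + 1) of 6.11 against 4.91 and 5.02 in S phase and of 7.03 against 5.56 and 5.61 in G2 and M phase. All day 3 libraries were above it (6.56 and 7.56 or more). Among pluripotency genes 11 of 35 measured members rose and 2 fell (adjusted p = 0.14). They were led by L1td1 at 9.1 ± 0.82 and Fgf4 at 9.58 ± 0.98. Among the largest increases were those of Aldh3a1 (10.36 ± 1.08), Podxl, a sialomucin of the cell surface (9.83 ± 0.69, to 1530 ± 220 CPM), and Pllp (9.55 ± 0.8). Fut9, which encodes a fucosyltransferase that can make the SSEA1 epitope, rose by 6.77 ± 0.71, adjusted p = 4.1e-08. Thy1, a fibroblast surface marker, changed by -4.56 ± 0.54. The glycolysis list fell (8 of 21 fell and 1 rose (9 fell adjusted over the list alone), adjusted p = 0.0025, adjusted p = 0.57 with an estimated correlation), Pdk1 among its members (-1.93 ± 0.25). The interferon list fell too (14 of 25 fell and 1 rose, adjusted p = 0.0025, adjusted p = 0.57 with an estimated correlation). In all, 5592 of 17326 genes were called, 2702 up and 2890 down in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. DESeq2's Wald test with its own scaling called 2078 genes up and 3453 down.

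By day 6, SSEA1pos cells had gained epithelial genes. Of their list 22 of 28 rose and 2 fell (adjusted p = 0.0013, adjusted p = 0.59 with an estimated correlation). Spint1, an inhibitor of epithelial serine proteases, reached 104 ± 43 CPM (9.46 ± 0.68, adjusted p = 9.2e-11). Cdh1 (E-cadherin) reached 152 ± 170 (6.4 ± 0.88) and Epcam 27.6 ± 20 (5.93 ± 0.66). Replicate 1 carried much of this gain, with Cdh1 at 354 CPM against 55.9 and 46.8 in replicates 2 and 3 and Epcam at 50.1 against 11.3 and 21.4. Without it these changes were 4.83 and 5.17 (adjusted p = 1.2e-05 and adjusted p = 2.9e-07). The epithelial list was at 4.06, 2.57 and 2.96 (mean log2(CPM + 1)), against 1.45 to 1.68 in MEFs. Snai2, a transcriptional repressor of Cdh1, changed by -6.48 ± 0.52. Nanog (ENSMUSG00000012396) stood at 26.2 ± 21 CPM against 1.17 ± 0.12 in MEFs (4.49 ± 0.94, adjusted p = 0.00034). In the unfolded protein and stress list 13 of 19 fell and 2 rose (adjusted p = 0.00013, adjusted p = 0.4 with an estimated correlation). Ddit3 was at -3.27 ± 0.34 and Herpud1, which acts in degradation at the endoplasmic reticulum, at -2.21 ± 0.27. At day 9 the pluripotency list had 32 of 35 rose and 1 fell (2 fell adjusted over the list alone) (adjusted p = 6.8e-09, adjusted p = 0.43 with an estimated correlation). Esrrb was at 8.08 ± 1.06, Sall4 at 8.76 ± 0.86 and Lin28a at 8.38 ± 1.18. Nanog stood at 148 ± 36 CPM (6.98 ± 1.01, adjusted p = 2.9e-06). Epcam had risen by 8.89 ± 0.7, to 215 ± 91 CPM, and Dnmt3b, a de novo DNA methyltransferase, by 4.58 ± 0.51. The fibroblast list had 32 of 34 fell and 0 rose (33 fell adjusted over the list alone) at day 6 (adjusted p = 2.3e-21, adjusted p = 0.031 with an estimated correlation). At day 9 34 of 34 fell and 0 rose (adjusted p = 8.8e-23, adjusted p = 0.024 with an estimated correlation). Totals were 5797 called genes at day 6 (2928 up, 2869 down) and 6685 at day 9 (3570 up, 3115 down).

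Against MEFs, day 12 SSEA1pos cells had most genes of the pluripotency list at higher levels. In the list 34 of 35 rose and 0 fell (adjusted p = 5.4e-12, adjusted p = 0.33 with an estimated correlation). Nanog was at 482 ± 64 CPM (8.69 ± 1.07, adjusted p = 1.9e-07), with Dppa5a at 10.48 ± 1.24, Zfp42 at 9.44 ± 1.19 and Esrrb at 10.36 ± 1.12. Dppa4, Nodal and Grhl2, at 0 reads in every MEF library, reached 56.9 ± 23, 38.1 ± 15 and 59.9 ± 13 CPM. Germline genes rose (20 of 24 rose and 0 fell (24 rose adjusted over the list alone), adjusted p = 6.5e-06, adjusted p = 0.33 with an estimated correlation), Tex19.1 by 10.18 ± 1.39. Hox genes fell (28 of 30 fell and 0 rose, adjusted p = 1.1e-11, adjusted p = 0.27 with an estimated correlation), Hoxd13 among them (-5.99 ± 0.51). In the DNA methylation list 9 of 13 rose and 0 fell (adjusted p = 0.011, adjusted p = 0.41 with an estimated correlation), Tet1 by 4.93 ± 0.74 and Dnmt3b by 4.98 ± 0.52. In the chromatin regulator list 11 of 24 rose and 0 fell (adjusted p = 7.5e-06, adjusted p = 0.33 with an estimated correlation), with the Polycomb cofactor Mtf2 at 3.2 ± 0.23. In iPS-stage SSEA1pos cells all 35 measured pluripotency genes were up (adjusted p = 1.5e-11, adjusted p = 0.44 with an estimated correlation). Nanog was at 1010 ± 410 CPM (9.76 ± 1.11) and Dppa5a at 1340 ± 370 (11.73 ± 1.28). Of the reprogramming factors, Myc fell below its MEF level, from 97.7 ± 9.2 to 5.15 ± 2.2 CPM (-4.24 ± 0.45, adjusted p = 1.1e-08), and Klf4 rose by 2.22 ± 0.38. The fibroblast list had 34 of 34 fell and 0 rose (adjusted p = 5.9e-20, adjusted p = 0.043 with an estimated correlation). It was led by Fstl1 (-6.41 ± 0.32) and Fbn1, a microfibril component (-8.94 ± 0.57). The germline list had 24 of 24 rose and 0 fell (adjusted p = 1.8e-09, adjusted p = 0.13 with an estimated correlation; Ddx4 6.94 ± 0.67, Stag3 6.4 ± 0.71). Called genes numbered 8080 at day 12 (4588 up, 3492 down) and 8741 at the iPS stage (4842 up, 3899 down).

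Xist, the RNA that coats the inactive X chromosome, was lower in iPS-stage SSEA1pos libraries (17.1, 48.2 and 12.1 CPM) than in MEFs (224, 495 and 503 CPM), a log2 fold change of -3.98 ± 0.78, adjusted p = 8.9e-05. The median change of 395 X-linked genes from MEFs exceeded that of 10760 autosomal genes by 0.59 log2 units at this stage, by 0.27 at day 12 and by 0 at day 9. In SSEA1neg cells this excess was 0.2, 0.23, 0.22, 0.18 and 0.35 at days 3, 6, 9, 12 and the iPS stage. With each library's GC trend removed these values were -0.02, 0.05, 0.07, 0.11 and 0.25, and that of iPS-stage SSEA1pos cells was 0.55. Xist stood at 547, 921 and 158 CPM in the iPS-stage SSEA1neg replicates 1, 2 and 3, with an excess of 0.28, 0.44 and 0.31 before removal of the GC trend. No read was counted in any of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty in any of the 33 libraries.

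**Figure D2:**
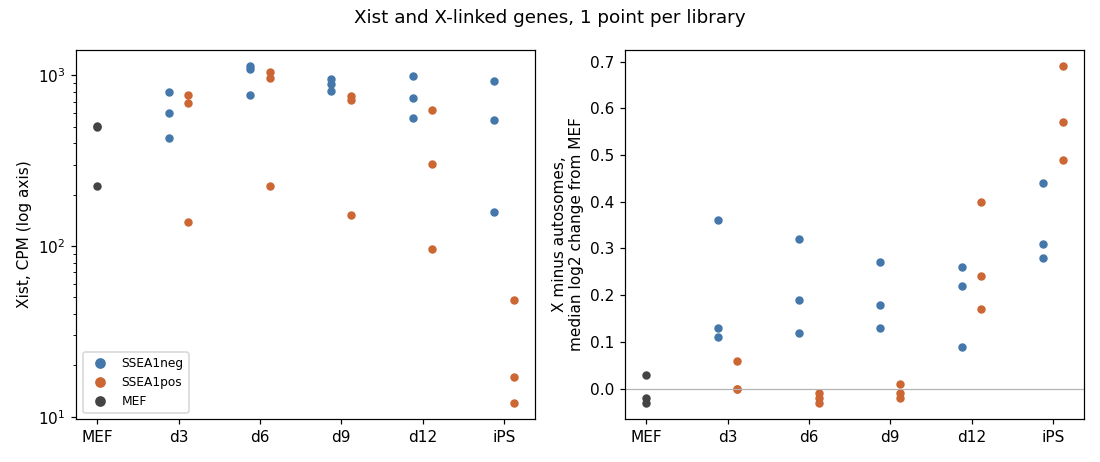
Left, Xist in CPM on a log axis; right, the median log2 change of X-linked genes from MEFs minus that of autosomal genes; 1 point per library, by stage, coloured by fraction. The iPS-stage SSEA1pos libraries have the lowest Xist (12.1 to 48.2 CPM) and the highest X-linked excess (0.49 to 0.69), against 0.09 to 0.44 in the SSEA1neg libraries of all stages.

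SSEA1neg cells had also left the MEF state by day 3. In the fibroblast list 27 of 34 fell and 0 rose (adjusted p = 7.5e-13, adjusted p = 0.12 with an estimated correlation). Col1a1 went to 578 ± 430 CPM (-6.02 ± 0.99, adjusted p = 3e-05). Cell-cycle genes were up (17 of 20 rose and 0 fell in S phase, adjusted p = 2.1e-06, adjusted p = 0.6 with an estimated correlation). In G2 and M phase 19 of 20 rose and 0 fell (adjusted p = 1.9e-08, adjusted p = 0.6 with an estimated correlation). Respiratory chain genes were up too (11 of 30 rose and 0 fell, adjusted p = 1.3e-06, adjusted p = 0.66 with an estimated correlation). Pou5f1 stood at 78.2 ± 26 CPM (4.47 ± 0.78) and L1td1 had risen by 8.31 ± 0.8. The pluripotency list as a group was not called (7 of 35 rose and 3 fell (5 rose and 2 fell adjusted over the list alone), adjusted p = 0.98). At day 6 the S phase list was not called against MEFs (2 of 20 rose and 1 fell, adjusted p = 0.18). Its mean log2(CPM + 1) was 5.53, 5.69 and 6.24 in these libraries, above MEF replicates 2 and 3 (4.91 and 5.02) but around that of MEF replicate 1 (6.11). Glycolysis genes were lower (14 of 21 fell and 3 rose, adjusted p = 7.6e-06, adjusted p = 0.59 with an estimated correlation; Pfkl -3.4 ± 0.34). Spint1 (7.26 ± 0.68, adjusted p = 1.4e-08), the basal epithelial regulator Trp63 (4.87 ± 0.96) and the interferon-induced Oas2 (5.25 ± 0.76) were higher at day 6. Trib3 (-6.19 ± 0.93) and Chac1 (-5.82 ± 0.85), targets of the stress factor ATF4, were lower. Called genes numbered 5225 at day 3 (2651 up, 2574 down) and 4888 at day 6 (2733 up, 2155 down). At day 3 DESeq2's Wald test called 2071 genes up and 3130 down. Genes of over 62% GC content (161 measured) had a median log2 change from MEFs of -1.14 at day 3 and -0.73 to -0.8 later. Removing each library's GC trend left 76.3% of the day 3 calls.

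Later SSEA1neg cells carried epithelial genes while most mesenchymal genes stayed below MEF levels. At day 9 21 of 28 rose and 2 fell (22 rose adjusted over the list alone) in the epithelial list (adjusted p = 0.00082, adjusted p = 0.96 with an estimated correlation). Epcam was at 21.9 ± 14 CPM (5.58 ± 0.66, adjusted p = 4.2e-07). At day 12 23 of 28 rose and 1 fell (adjusted p = 1.8e-07, adjusted p = 0.53 with an estimated correlation). The pluripotency list rose to 29 of 35 rose and 2 fell (30 rose adjusted over the list alone) at day 12 (adjusted p = 2.4e-06, adjusted p = 0.69 with an estimated correlation), with Nanog at 25.2 ± 18 CPM (4.43 ± 0.94). The fibroblast list had 24 of 34 fell and 0 rose (adjusted p = 1.4e-11, adjusted p = 0.34 with an estimated correlation). At the iPS stage SSEA1neg cells had genes of several lineages. In the pluripotency list 32 of 35 rose and 0 fell (33 rose adjusted over the list alone) (adjusted p = 1.6e-11, adjusted p = 0.4 with an estimated correlation). The trophoblast list had 12 of 17 rose and 0 fell (13 rose adjusted over the list alone) (adjusted p = 0.0012, adjusted p = 0.25 with an estimated correlation), with Eomes at 7.05 ± 1.21. The keratinocyte list had 11 of 18 rose and 0 fell (adjusted p = 0.0057, adjusted p = 0.65 with an estimated correlation), with Trp63 at 5.69 ± 0.98. Germline genes had 21 of 24 rose and 0 fell (22 rose adjusted over the list alone) (adjusted p = 2.4e-08, adjusted p = 0.25 with an estimated correlation). Gata4, a transcription factor of endoderm and heart, was at 23.6 ± 13 CPM (4.79 ± 0.85, adjusted p = 0.00011) and Otx2 at 59.9 ± 19 (9.94 ± 0.88). Col1a1 was still at 3680 ± 2300 CPM (-3.35 ± 0.88). Nanog was uneven in this group, at 21.4, 59.5 and 441 CPM in replicates 1, 2 and 3. So were the pluripotency (3.02, 3.87 and 6.13), trophoblast (3.3, 3.6 and 2.52) and keratinocyte lists (2.62, 3.39 and 1.59, mean log2(CPM + 1)). There were 4602 called genes at day 9 (2585 up, 2017 down), 4875 at day 12 (2944 up, 1931 down) and 4636 at the iPS stage (3302 up, 1334 down). Fitted on the MEF and iPS-stage SSEA1neg libraries alone, the last comparison called 2745.

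**Figure D3:**
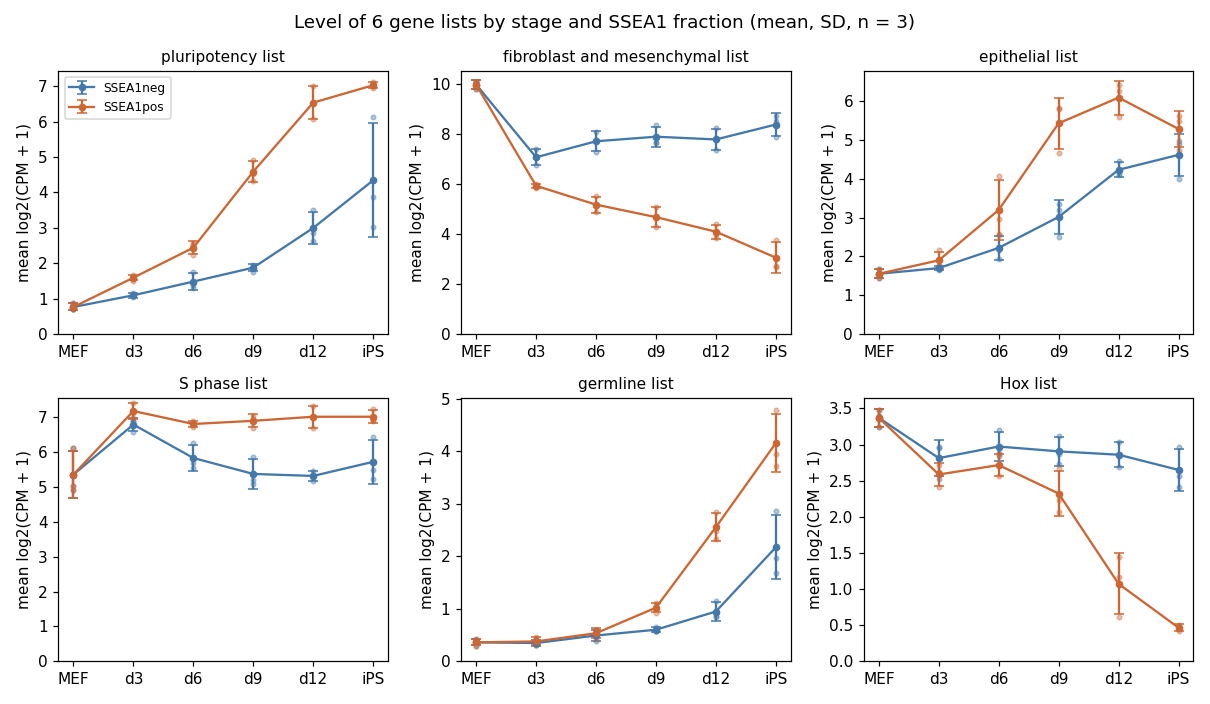
Mean log2(CPM + 1) over the members of 6 gene lists, by stage, in SSEA1neg and SSEA1pos cells (both lines start at the MEF libraries). Large points are means, bars the SD of 3 libraries, small points single libraries. The pluripotency list reached 7.02 ± 0.08 in iPS-stage SSEA1pos cells and 4.34 ± 1.61 in SSEA1neg cells, and the Hox list 0.47 ± 0.04 and 2.65 ± 0.29.

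Within a stage, the sort compared SSEA1pos with SSEA1neg cells. At day 3 the SSEA1pos fraction had more of the reprogramming factors and less of the fibroblast programme. Sox2 was at 344 ± 25 against 25.7 ± 19 CPM (3.74 ± 0.74, adjusted p = 0.0022). Klf4 was at 627 ± 62 against 124 ± 14 (2.34 ± 0.38, adjusted p = 0.00052). Of the 4 factors, 3 of 4 rose and 0 fell (4 rose adjusted over the list alone) (adjusted p = 0.00013, adjusted p = 0.33 with an estimated correlation). Fut9 was higher (39.8 ± 7.5 against 5.86 ± 5.1 CPM, 2.77 ± 0.52). Thy1 was lower (39.7 ± 23 against 277 ± 83 CPM, -2.8 ± 0.5). Of the fibroblast list, 8 of 34 fell and 0 rose (16 fell adjusted over the list alone) (adjusted p = 1.8e-06, adjusted p = 0.55 with an estimated correlation). Lox, a collagen cross-linking enzyme, was at -4.26 ± 0.96 and Snai2 at -2.28 ± 0.43. Chemokine genes were lower in SSEA1pos cells, Cxcl5 by -5.39 ± 1.08 and Cxcl12 by -4.97 ± 0.83. Cxcl5 stood at 13.1, 275 and 36 CPM in SSEA1neg replicates 1, 2 and 3, and its difference was -3.25 (adjusted p = 0.033) without replicate 2. That library also had the most of the macrophage gene Lyz2 in its group (0.203, 22.4 and 1.54 CPM). Of the inflammation list 6 of 23 fell and 0 rose (8 fell adjusted over the list alone) (adjusted p = 0.0037, adjusted p = 1 with an estimated correlation). Few pluripotency genes differed yet (5 of 35 rose and 0 fell, adjusted p = 0.0035, adjusted p = 1 with an estimated correlation; Sall1 3.03 ± 0.36, Trim71 2.98 ± 0.51). The chromatin regulators had 5 of 24 rose and 0 fell (adjusted p = 9e-07, adjusted p = 0.55 with an estimated correlation). The largest increase was in Scand1 (6.87 ± 1.32), which stood at 0 to 1.78 CPM in every SSEA1neg library of the series and at 8.13 CPM or more elsewhere. Genes of over 62% GC had a median log2 difference of 0.9 at this stage. In all 1155 genes were called, 478 up and 677 down. With each library's GC and length trends removed 205 rose and 556 fell. With a replicate block and the GC trend removed 359 rose and 922 fell. Without day 3 SSEA1pos replicate 3 or day 3 SSEA1neg replicate 2 the total was 531 or 689.

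At day 6 the sort divided cells by mesenchymal against epithelial genes. In the fibroblast list 26 of 34 measured members fell and 0 rose (adjusted p = 1.6e-14, adjusted p = 0.16 with an estimated correlation). Postn was at 0.707 ± 0.13 against 114 ± 79 CPM (-7.32 ± 0.94, adjusted p = 9.2e-06). Col1a1 was at -5.61 ± 0.98 and the growth factor receptor gene Pdgfrb at -4.71 ± 0.65. In the epithelial list 16 of 28 rose and 1 fell (18 rose adjusted over the list alone) (adjusted p = 0.00032, adjusted p = 0.69 with an estimated correlation). Grhl2, an epithelial transcription factor, rose by 4.42 ± 0.76, Lsr by 3.43 ± 0.45 and Epcam by 2.53 ± 0.49, while P-cadherin (Cdh3) was lower (-2.79 ± 0.51). Proliferation genes were higher in SSEA1pos cells, with 11 of 20 rose and 0 fell in the G2 and M phase list (adjusted p = 1.5e-07, adjusted p = 0.5 with an estimated correlation). Kif20a, a gene of cytokinesis, rose by 1.46 ± 0.31. In the S phase list 8 of 20 rose and 0 fell (adjusted p = 7.2e-06, adjusted p = 0.54 with an estimated correlation). Interferon genes were lower (13 of 25 fell and 0 rose (14 fell adjusted over the list alone), adjusted p = 8.7e-05, adjusted p = 0.48 with an estimated correlation), Zbp1 by -4.12 ± 0.8. Inflammation genes were lower too (16 of 23 fell and 0 rose, adjusted p = 3e-06, adjusted p = 0.39 with an estimated correlation), with the matrix protease gene Mmp3 at -10.86 ± 1.69. The macrophage and leukocyte list had 4 of 21 fell and 0 rose (0 fell adjusted over the list alone) (adjusted p = 0.084, adjusted p = 0.00017 with the replicate block). Lyz2 stood at 113 CPM in day 6 SSEA1neg replicate 2, 15 in replicate 3 and 0.27 in replicate 1. The inflammation list was also highest in replicate 2 (mean log2(CPM + 1) of 4.97, against 3.76 and 3.6), and at 1.51 to 2.3 in SSEA1pos libraries. Utf1 was among the largest increases (12.3 ± 9.5 against 0.192 ± 0.16 CPM, 5.86 ± 1.18). Pluripotency genes had 13 of 35 rose and 0 fell (14 rose adjusted over the list alone) (adjusted p = 0.00026, adjusted p = 0.75 with an estimated correlation). The comparison called 2847 genes, 1094 up and 1753 down, and genes of over 62% GC had a median log2 difference of 0.84.

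At day 9 pluripotency genes separated the fractions, as 28 of 35 rose and 0 fell (29 rose adjusted over the list alone) (adjusted p = 2.8e-11, adjusted p = 0.24 with an estimated correlation). Nanog was at 148 ± 36 against 6.78 ± 2.6 CPM (4.46 ± 0.85, adjusted p = 0.00025). Esrrb was at 99 ± 23 against 4.41 ± 0.8 (4.49 ± 0.81), and Sall4 at 74.1 ± 18 against 1.5 ± 0.68 (5.65 ± 0.65). Utf1 and Lin28a were higher by 6.66 ± 1.1 and 5.37 ± 0.84. Epithelial genes were higher in SSEA1pos cells (23 of 28 rose and 0 fell, adjusted p = 1.9e-10, adjusted p = 0.24 with an estimated correlation), Cldn4, a tight junction claudin, by 3.8 ± 0.56. All but 1 of the measured fibroblast genes were lower (33 of 34 fell and 0 rose, adjusted p = 3.2e-18, adjusted p = 0.065 with an estimated correlation), Snai2 by -4.7 ± 0.5 and Thy1 by -4.24 ± 0.54. Cell-cycle lists differed as at day 6 (19 of 20 rose and 0 fell in G2 and M phase, adjusted p = 2.8e-11, adjusted p = 0.24 with an estimated correlation). In S phase 16 of 20 rose and 0 fell (adjusted p = 1.3e-08, adjusted p = 0.24 with an estimated correlation), with Mcm2 at 2.22 ± 0.38. TGF-beta response genes were lower (15 of 20 fell and 0 rose, adjusted p = 3.2e-08, adjusted p = 0.13 with an estimated correlation). Hox genes were lower too (8 of 30 fell and 0 rose, adjusted p = 0.0061, adjusted p = 0.63 with an estimated correlation), Hoxc8 by -2.93 ± 0.51. The macrophage and leukocyte list had 8 of 21 fell and 0 rose (9 fell adjusted over the list alone) (adjusted p = 0.063, adjusted p = 0.00013 with the replicate block). SSEA1neg replicate 2 stood apart in it, with a mean log2(CPM + 1) of 3.62 against 1.13 and 1.65 in replicates 1 and 3 and 0.8 to 1 in SSEA1pos libraries. Called genes numbered 4374, 1999 up and 2375 down, beside a median log2 difference of 0.76 for genes of over 62% GC.

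At day 12 the fractions differed in 6227 called genes, 3114 up and 3113 down. In the pluripotency list 34 of 35 rose and 0 fell (adjusted p = 1e-13, adjusted p = 0.29 with an estimated correlation). Nanog stood at 482 ± 64 against 25.2 ± 18 CPM (4.26 ± 0.83, adjusted p = 0.00017), Utf1 at 293 ± 57 against 5.05 ± 3.1 (5.86 ± 1.02). Zfp42 and Esrrb were higher by 4.59 ± 0.85 and 4.71 ± 0.8. Vim, the mesenchymal intermediate filament, was at 376 ± 150 against 4170 ± 720 CPM (-3.47 ± 0.37, adjusted p = 1.5e-07). Prrx1, a limb mesenchyme transcription factor, was at 7.02 ± 3.1 against 264 ± 68 (-5.24 ± 0.54). In the fibroblast list 33 of 34 fell and 0 rose (adjusted p = 7e-17, adjusted p = 0.096 with an estimated correlation). Hox genes were lower in SSEA1pos cells (26 of 30 fell and 0 rose (27 fell adjusted over the list alone), adjusted p = 1.9e-11, adjusted p = 0.2 with an estimated correlation; Hoxa11 -3.99 ± 0.37, Hoxd13 -4.58 ± 0.49). Germline genes were higher (19 of 24 rose and 0 fell (20 rose adjusted over the list alone), adjusted p = 2.6e-06, adjusted p = 0.29 with an estimated correlation; Mael 4.51 ± 0.8, Stag3 3.22 ± 0.6). Slc2a3, a glucose transporter gene, was higher by 2.51 ± 0.36 in a glycolysis list with 12 of 21 rose and 1 fell (adjusted p = 0.0071, adjusted p = 0.49 with an estimated correlation). The primitive endoderm list had 7 of 18 fell and 2 rose (adjusted p = 0.043, adjusted p = 0.49 with an estimated correlation; adjusted p = 0.061 with the replicate block). SSEA1pos replicate 1 stood apart in this list, with a mean log2(CPM + 1) of 4.2 against 3.05 and 3.1 in replicates 2 and 3 and 4.22 to 4.49 in SSEA1neg libraries. The endoderm genes Foxa2 and Cer1, chosen after their values were seen, were at 27.5 and 67.9 CPM in it and at 0.723 CPM or less in replicates 2 and 3. The cell cycle inhibitor genes Cdkn2b (-3.36 ± 0.65) and Cdkn1a (-1.77 ± 0.45) were lower. For the macrophage and leukocyte list 3 of 21 fell and 0 rose (0 fell adjusted over the list alone) (adjusted p = 0.19, adjusted p = 0.0071 with the replicate block). It stood at 1.09, 3.48 and 1.73 in SSEA1neg replicates 1, 2 and 3 and at 0.88 to 1.3 in SSEA1pos libraries. Genes of over 62% GC had a median log2 difference of 0.58.

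**Figure D4:**
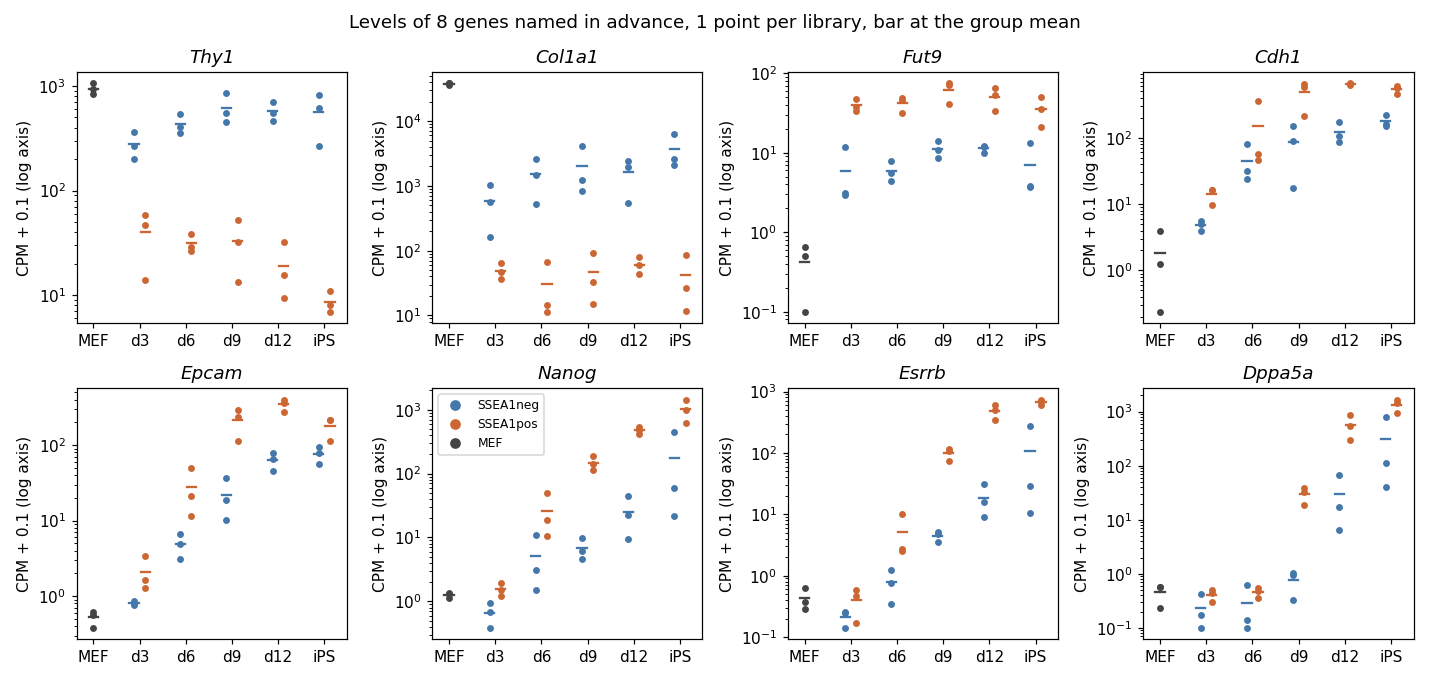
Levels of 8 genes named in advance (CPM + 0.1 on a log axis) by stage. Each point is 1 library, each short line a group mean, coloured by fraction. From day 3 on, every SSEA1pos library lay below every SSEA1neg library of its stage for Thy1 and Col1a1 and above for Fut9. Replicate 3 of the iPS-stage SSEA1neg group has the group's highest Nanog, at 441 CPM.

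At the iPS stage the fractions differed in mesenchymal, Hox and imprinted genes as well as in pluripotency genes. The secreted protein gene Fstl1 stood at 39.3 ± 15 CPM in SSEA1pos and 1600 ± 440 in SSEA1neg cells (-5.34 ± 0.31, adjusted p = 1.4e-11). In the fibroblast list 34 of 34 fell and 0 rose (adjusted p = 2.6e-20, adjusted p = 0.035 with an estimated correlation), Prrx1 and Cd44 by -7.66 ± 0.62 and -6.75 ± 0.58. TGF-beta response genes were lower (17 of 20 fell and 0 rose, adjusted p = 1.2e-11, adjusted p = 0.036 with an estimated correlation; Tgfb3 -7.07 ± 0.59). Hox genes were lower as well (29 of 30 fell and 0 rose, adjusted p = 1.6e-14, adjusted p = 0.13 with an estimated correlation; Hoxa11 -7.08 ± 0.49). In the pluripotency list 27 of 35 rose and 0 fell (29 rose adjusted over the list alone) (adjusted p = 3.9e-11, adjusted p = 0.34 with an estimated correlation), Tfcp2l1 at 673 ± 65 against 87.9 ± 96 CPM (2.94 ± 0.54). Nanog was at 1010 ± 410 against 174 ± 230 CPM (2.54 ± 0.77, adjusted p = 0.0077). This difference was no longer called when only these libraries were fitted (2.4, adjusted p = 0.098) or without SSEA1neg replicate 2 (2.1, adjusted p = 0.051). Genes of primitive endoderm were lower in SSEA1pos cells (11 of 18 fell and 1 rose (2 rose and 14 fell adjusted over the list alone), adjusted p = 0.00074, adjusted p = 0.32 with an estimated correlation), Sparc by -4.02 ± 0.43. Immediate early genes were lower (12 of 20 fell and 1 rose, adjusted p = 0.004, adjusted p = 0.45 with an estimated correlation), and so were imprinted genes (11 of 18 fell and 1 rose (12 fell adjusted over the list alone), adjusted p = 0.0069, adjusted p = 0.45 with an estimated correlation). The mean log2(CPM + 1) of the imprinted list was 7.35, 6.61 and 4.89 in SSEA1neg replicates 1, 2 and 3 and 4.57 to 5.06 in the SSEA1pos libraries, so that SSEA1neg replicate 3 lay within the SSEA1pos range. Germline genes were higher (19 of 24 rose and 0 fell (22 rose adjusted over the list alone), adjusted p = 4e-08, adjusted p = 0.19 with an estimated correlation; Ddx4 3.01 ± 0.52). Xist differed by -4.39 ± 0.8 and Myc by -2.83 ± 0.42. Of 6475 called genes 2777 rose and 3698 fell. With only these groups fitted the split was 1372 to 3030, and without SSEA1neg replicate 2 it was 1755 to 3274. Genes of over 62% GC had a median log2 difference of 0.57, and Scand1 one of 5.19 ± 1.21.

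Successive stages of SSEA1pos cells were compared next. From day 3 to day 6 epithelial genes rose (13 of 28 rose and 0 fell (19 rose adjusted over the list alone), adjusted p = 8.5e-11, adjusted p = 0.56 with an estimated correlation). Spint1 went from 4.57 ± 2 to 104 ± 43 CPM (4.5 ± 0.46, adjusted p = 3.4e-06) and Epcam from 2 ± 1.1 to 27.6 ± 20 (3.75 ± 0.53). Pluripotency genes rose in part (9 of 35 rose and 0 fell (12 rose adjusted over the list alone), adjusted p = 0.00022, adjusted p = 0.99 with an estimated correlation). Sall4 was at 4.01 ± 0.66, Nr5a2 at 5.62 ± 1.05 and Tfcp2l1 at 3.13 ± 0.58. Cyp26b1, a retinoic acid hydroxylase, was among the largest decreases (-5.83 ± 0.6, adjusted p = 3.4e-06). The mesenchymal repressors Snai2 (-2.17 ± 0.46) and Twist2 (-3.93 ± 0.79) fell further. This step called 773 genes (556 up, 217 down), or 352 with only these groups fitted. It called 205, 490, 513 or 330 without day 3 replicate 1, day 3 replicate 2, day 6 replicate 2 or day 6 replicate 3.

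From day 6 to day 9 nearly all called genes rose, 173 of 187. Dppa5a went from 0.362 ± 0.093 to 30.2 ± 11 CPM (6.36 ± 1.08, adjusted p = 0.0019) and Lin28a from 0.528 ± 0.37 to 30 ± 18 (5.8 ± 0.88). Dppa3 changed by 7.71 ± 1.2 and Prdm14 by 6.32 ± 1.06. The pluripotency list rose (15 of 35 rose and 0 fell (26 rose adjusted over the list alone), adjusted p = 4.2e-34, adjusted p = 0.049 with an estimated correlation). The epithelial list rose too (13 of 28 rose and 0 fell (24 rose adjusted over the list alone), adjusted p = 5.7e-42, adjusted p = 0.0073 with an estimated correlation). Adgra2, an adhesion receptor gene, was among the 14 that fell (-2.33 ± 0.39, adjusted p = 0.0016). The count was 43 with only these groups fitted, 394 with DESeq2's Wald test and 312 with a replicate block and the GC trend removed. It was 51, 92, 116 or 72 without day 6 replicate 2, day 6 replicate 3, day 9 replicate 1 or day 9 replicate 3.

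In the step to day 12 germline and pluripotency genes rose and Hox genes fell. Otx2 rose from 2.91 ± 1.5 to 51.5 ± 13 CPM (4.15 ± 0.56, adjusted p = 9.2e-05). Tbx3 rose from 10 ± 1.7 to 129 ± 40 (3.69 ± 0.59) and Dppa5a from 30.2 ± 11 to 566 ± 280 (4.23 ± 0.86). In the pluripotency list 17 of 35 rose and 0 fell (25 rose adjusted over the list alone) (adjusted p = 1e-16, adjusted p = 0.31 with an estimated correlation). In the germline list 16 of 24 rose and 0 fell (20 rose adjusted over the list alone) (adjusted p = 9.9e-15, adjusted p = 0.076 with an estimated correlation; Mael 6.88 ± 0.98, Ddx4 3.7 ± 0.57). Hox genes had 21 of 30 fell and 0 rose (25 fell adjusted over the list alone) (adjusted p = 5.5e-19, adjusted p = 0.076 with an estimated correlation). Hoxa11 went from 6.28 ± 2.2 to 0.905 ± 0.58 CPM (-2.81 ± 0.36) and Hoxd13 changed by -3.18 ± 0.47. Vim fell from 1910 ± 640 to 376 ± 150 CPM (-2.35 ± 0.35). Called genes numbered 1528 (930 up, 598 down). They numbered 578, 879, 682 and 1012 without day 12 replicate 1, day 9 replicate 1, day 9 replicate 2 and day 12 replicate 2. With only these groups fitted the split was 889 to 363.

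Between day 12 and the iPS stage no pluripotency gene of the list was called in either direction, though the list test placed it higher (adjusted p = 0.027, adjusted p = 0.82 with an estimated correlation). Myc fell from 553 ± 250 to 5.15 ± 2.2 CPM (-6.74 ± 0.5, adjusted p = 4.9e-09), with Shisa3 (-7.34 ± 0.77) and Alox15 (-7.72 ± 1.06) among the largest decreases. Germline genes rose further (13 of 24 rose and 0 fell (19 rose adjusted over the list alone), adjusted p = 1.1e-15, adjusted p = 0.06 with an estimated correlation). Ddx4 went to 31.6 ± 7.6 CPM (2.67 ± 0.51) and Taf7l to 17.6 ± 13 (3.73 ± 0.62). Hox genes fell further (19 of 30 fell and 1 rose (21 fell adjusted over the list alone), adjusted p = 9.7e-08, adjusted p = 0.49 with an estimated correlation; Hoxa10 -3.22 ± 0.44). The 4 measured genes of the 2-cell-like list had 3 of 4 rose and 0 fell (4 rose adjusted over the list alone) (adjusted p = 0.00011, adjusted p = 0.06 with an estimated correlation), at a mean log2(CPM + 1) of 1.08, 0.53 and 2.44 in iPS-stage replicates 1, 2 and 3. The imprinted gene Grb10 (-2.24 ± 0.26) and the fibroblast genes Fstl1 (-3.23 ± 0.28) and Cd44 (-3.44 ± 0.51) were lower. Xist went from 341 ± 270 to 25.8 ± 20 CPM (-3.73 ± 0.77). Of 1645 called genes 648 rose and 997 fell, 871 in all without day 12 replicate 3. The increases were 283, 292 or 388 without day 12 replicate 2, day 12 replicate 3 or iPS-stage replicate 3. With only these groups fitted 825 rose and 616 fell.

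Whether the SSEA1pos against SSEA1neg difference itself changed from day 3 to day 12 was tested as an interaction. The fractions moved apart in mesenchymal genes, with 19 of 34 fell and 0 rose (23 fell adjusted over the list alone) of the fibroblast list (adjusted p = 5.2e-15, adjusted p = 0.14 with an estimated correlation). Vim was at -3.46 ± 0.48, adjusted p = 0.00017 and Prrx1 at -4.3 ± 0.67. They moved apart in Hox genes as well (19 of 30 fell and 0 rose (25 fell adjusted over the list alone), adjusted p = 3.7e-15, adjusted p = 0.14 with an estimated correlation; Hoxd13 -4.76 ± 0.62). Cell-cycle genes gained in SSEA1pos relative to SSEA1neg cells, with Bub1 at 2.18 ± 0.49 (18 of 20 rose and 0 fell (19 rose adjusted over the list alone) in G2 and M phase, adjusted p = 1.6e-10, adjusted p = 0.38 with an estimated correlation). From day 3 to day 12 the mean log2(CPM + 1) of this list went from 7.68 to 5.91 in SSEA1neg cells. In SSEA1pos cells it went from 7.95 to 7.76, so their own level did not rise. Chromatin regulators also gained in SSEA1pos relative to SSEA1neg cells, with Mtf2 at 2.34 ± 0.3 and Ezh2 at 1.63 ± 0.38 (8 of 24 rose and 0 fell (9 rose adjusted over the list alone), adjusted p = 7e-06, adjusted p = 0.38 with an estimated correlation). The pluripotency list had 6 of 35 rose and 0 fell (adjusted p = 0.00032, adjusted p = 0.65 with an estimated correlation; Tbx3 4.29 ± 0.79). The growth regulator pair H19 (-4.46 ± 1.06) and Igf2 (-4.74 ± 1.24), an imprinted locus, shifted toward the SSEA1neg fraction. The imprinted list had 4 of 18 fell and 0 rose (5 fell adjusted over the list alone) (adjusted p = 0.042, adjusted p = 0.65 with an estimated correlation). In all 2450 genes were called, 1076 up and 1374 down. The total was 1536 (578 up) without day 12 SSEA1pos replicate 1, and 700 were up without day 3 SSEA1pos replicate 2.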

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

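The tests in this part were chosen before their results were seen. The change of the SSEA1pos minus SSEA1neg difference from day 3 to day 12, tested as an interaction, called 2450 genes. Of 100 splits of the same libraries, 10 called at least as many genes as the real one when the 12 libraries were fitted alone (real split 2648, highest other 6667), so chance was not excluded by this count. All 9 other such splits kept the day 12 fractions intact, so their counts carry the day 12 difference itself. Of these 8 mixed the day 3 fractions. The other, with the highest count, exchanged the day 3 labels as a whole, so that it called the sum of both sort differences instead of their change. The highest count among splits that kept neither stage intact was 0, but such splits put the sort differences into the spread.

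Single genes with a difference between the stages were, toward higher in SSEA1pos cells at day 12, Foxd3 (8.63 ± 2.68), Tnk1 (7.28 ± 1.34), Vwf (7.08 ± 1.21), Apoc1 (7.05 ± 2.11), Grin1 (6.64 ± 1.43) and Zfp42 (4.24 ± 1.42). Toward lower were the multi-copy RNA n-R5-8s1 (-7.46 ± 1.94), Tlx2 (-6.63 ± 1.38), Col6a1 (-5.08 ± 0.85), Nxpe2 (-4.89 ± 0.8), Rn7sk (-4.87 ± 1.55), Plscr2 (-4.85 ± 0.87), Itga4 (-3.33 ± 1.03), Fut4 (-1.86 ± 0.63) and Thy1 (-2.12 ± 0.67), all log2 values with standard errors from edgeR. Foxd3, Tnk1 and Apoc1 had no read in any day 3 SSEA1pos library, so their fitted values depend on the prior count and are no bounds. In the day 12 SSEA1pos replicates 1, 2 and 3 they stood at 38.1, 32.8 and 15 CPM (Foxd3), 14.4, 26.2 and 24.7 (Tnk1) and 26.7, 29.1 and 22.9 (Apoc1). With the settings run, the calls of Tnk1, Tlx2, Col6a1, Nxpe2 and Plscr2 were not lost. Calls were lost without single libraries for Grin1 (day 3 SSEA1neg replicate 2, 5.22), n-R5-8s1 (day 12 SSEA1neg replicate 3, -1.84, a library with 934 CPM) and Rn7sk (the same library, -0.56; also day 3 SSEA1neg 1 and 3, day 3 SSEA1pos 2 and 3 and each day 12 SSEA1pos library, -5.15 to -4.34). The call of Foxd3 was lost without day 3 SSEA1neg 1 or 3, day 3 SSEA1pos 1 or 3, or day 12 SSEA1pos 1 (7.55 to 8.64). That of Apoc1 was lost without day 3 SSEA1neg 2 or 3 or day 3 SSEA1pos 1 (6.81 to 6.99). Zfp42 lost its call without any of the 12 libraries but day 12 SSEA1neg 2 and day 12 SSEA1pos 3 (3.76 to 4.61). Itga4 lost it without day 3 SSEA1neg 2 or 3, day 12 SSEA1neg 1, day 3 SSEA1pos 1, or day 12 SSEA1pos 1 or 2 (-3.39 to -2.96). Thy1 lost it without day 3 SSEA1neg 1 or 3, day 12 SSEA1neg 2, day 3 SSEA1pos 2 or 3, or day 12 SSEA1pos 1 or 2 (-2.13 to -1.78), and Fut4 did without any library but day 12 SSEA1pos 1 (-2.02 to -1.6). With every library thinned to the smallest total, Foxd3 (7.19), Vwf (4.53), Apoc1 (5.32), Zfp42 (5.54), Rn7sk (-4.66) and Fut4 (-1.87) were not called. With no filter on low counts, calls were lost for Foxd3 (8.46), Zfp42 (4.17), Itga4 (-3.41), Fut4 (-1.94) and Thy1 (-2.18). With only these 12 libraries fitted, Rn7sk (-4.87) and Thy1 (-2.15) were not called, and with the GC and length trends removed, a setting chosen after the data were seen, Fut4 (-1.75) was not.

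Reads assigned to no annotated gene took 5.8 ± 0.34% of uniquely aligned reads in MEFs (5.54 to 6.19%). Whether they lay within or outside genes was not tested. The group means of the later stages were above the highest MEF library, at 6.27 ± 0.85, 9.72 ± 0.37, 10.69 ± 0.72, 13.19 ± 2.02 and 9.76 ± 2.01% in SSEA1neg cells of days 3, 6, 9, 12 and the iPS stage, and at 6.76 ± 2.04, 8.45 ± 2.2, 8.92 ± 2.21, 10.48 ± 2.44 and 10.67 ± 1.42% in SSEA1pos cells. Single libraries overlapped MEFs, namely day 3 SSEA1neg replicate 2 (5.32%), day 3 SSEA1pos replicate 1 (4.42%) and day 6 SSEA1pos replicate 1 (5.92%), so that the day 3 groups and day 6 SSEA1pos cells were not separated from MEFs.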

How the results depend on the processing

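Removal of the GC trend, of the GC and length trends, and of the GC trend with a replicate block were chosen only after the data were seen; the other settings were planned. Some of 20 counts of called genes moved by over 1.5 times, and the cause was not tested. The day 3 sort went from 1155 to 761 (205 up, 556 down) with the GC and length trends removed. Day 9 against day 6 went from 187 to 394 with DESeq2's Wald test and 312 with a replicate block and the GC trend removed. With only the groups compared in the fit, so with fewer libraries to estimate the spread, SSEA1neg iPS-stage cells against MEFs went from 4636 to 2745, day 6 against day 3 from 773 to 352 and day 9 against day 6 from 187 to 43. The share of increases moved by over 10 points at the day 3 sort (41.4% to 26.8% without the GC trend, 26.9% without GC and length, 28% with the replicate block and no GC trend) and the iPS-stage sort (31.2% in a fit of those groups alone). It also moved for day 3 SSEA1pos against MEFs (37.6% by Wald, 38.1% without GC and length), day 3 SSEA1neg against MEFs (39.8% and 39.9%), and in fits of the groups alone day 12 against day 9 (71%) and iPS stage against day 12 (57.3%; 24.3% without day 12 replicate 2, against 39.4%). Where the total moved less, the increases moved by over 1.5 times at the day 3 sort without the GC trend (478 to 267), at the day 6 sort (1094 to 704) and in day 3 SSEA1neg cells against MEFs (2651 to 1719) without GC and length. They also did in day 6 against day 3 by Wald (556 to 838) or with the block and no GC trend (845), in the iPS stage against day 12 with the latter (648 to 996), at the iPS-stage sort in a fit of those groups alone (2777 to 1372) and in the interaction with no filter (1076 to 715). Decreases did in fits of the groups alone in day 12 against day 9 (598 to 363) and the iPS stage against day 12 (997 to 616), and with the block in day 9 against day 6 (14 to 32). With 1 library left out, sort counts were 531 to 1117, 2100 to 2906, 3346 to 4422, 5434 to 6400 and 5029 to 7802 from day 3 to the iPS stage. Those of SSEA1pos cells against MEFs were 4901 to 5470, 5189 to 5737, 6005 to 6483, 7482 to 8073 and 8406 to 8677, and those of SSEA1neg cells 4496 to 5280, 4081 to 5092, 3934 to 4349, 4152 to 4577 and 4032 to 4979. Steps ran from 205 to 902, 51 to 218, 578 to 1899 and 871 to 1799, and the interaction from 1536 to 2958. Of 126 such counts 16 moved by over 1.5 times. These were the day 3 sort without SSEA1pos 3 (531) or SSEA1neg 2 (689), day 6 against day 3 without day 3 replicate 1 (205) or 2 (490) or day 6 replicate 2 (513) or 3 (330). They were also day 9 against day 6 without day 6 replicate 2 (51) or 3 (92) or day 9 replicate 1 (116) or 3 (72), day 12 against day 9 without day 9 replicate 1 (879) or 2 (682) or day 12 replicate 1 (578) or 2 (1012), iPS stage against day 12 without day 12 replicate 3 (871), and the interaction without day 12 SSEA1pos replicate 1 (1536). Of the named genes only Sycp3 reversed, in the interaction with thinned libraries (-0.88, adjusted p = 0.53, the cause was not tested). The replicate block alone moved no count of called genes by over 1.5 times (day 9 against day 6 became 279). With it the sorts of days 3, 6, 9 and 12 called 1524, 3278, 4792 and 6620 genes. The main test had no block there, although the numbers paired the libraries. Where numbers paired the libraries the list calls it changed are given in the report. The numbers did not pair at the iPS-stage sort (r 0.07 to 0.3, 4 of 6 libraries closest to their own number), where the block called 6944. Nor did they pair in the interaction (r 0.02 to 0.47, 31 of 36 comparisons closest to their own number), where the block called 2894 and Zfp42 (4.22), or Zfp42 (4.19) and Rn7sk (-4.26) with the GC trend also removed, were not called. With an estimated correlation 220 of 600 list tests lost their call and none gained one. The 600 also hold tests that had no call to lose, so the share of list calls lost was larger than these numbers give. Of named-gene tests 2603 kept their side of the threshold when thinned to the smallest total, 65 lost and 19 gained a call, so lower depth ended more calls than it added.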

Other observations

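The tests of GC content and the genes named library by library in this part were chosen only after the results were seen. The tests on the iPS-stage SSEA1neg library, on the X chromosome and on other splits were set before their own results were seen. That on the iPS-stage SSEA1neg library concerns replicate 3, which was picked by its levels in these data. Endothelial genes went both ways in SSEA1pos cells against MEFs. At day 3 4 of 15 measured members fell and 2 rose (adjusted p = 0.62), yet Tek, the gene of an angiopoietin receptor, rose from 3.27 ± 2.2 to 224 ± 19 CPM (6.06 ± 0.47, adjusted p = 6.2e-10). At day 12 10 of 15 measured members rose and 3 fell (adjusted p = 0.35). Laptm5, a lysosomal membrane protein gene of blood cells, rose at day 3 from 12.5 ± 17 to 365 ± 100 CPM (4.87 ± 0.75, adjusted p = 8.8e-06), within a macrophage and leukocyte list with 7 of 21 fell and 2 rose (4 fell adjusted over the list alone) (adjusted p = 0.26; adjusted p = 0.011 with the replicate block). The mean log2(CPM + 1) of that list was 0.64, 3.42 and 1.53 in MEF replicates 1, 2 and 3. It was 0.92, 1.06 and 0.81 in the day 3 SSEA1pos replicates, so MEF replicate 1 lay below all of them. Vwf, the gene of von Willebrand factor, rose from day 9 to day 12 (4.69 ± 0.57, adjusted p = 3.9e-05).

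Lists of other lineages and programmes differed in some of their members. Between the iPS-stage fractions the neural list had 10 of 19 fell and 1 rose (2 rose adjusted over the list alone) (adjusted p = 0.5) and the keratinocyte list 11 of 18 fell and 1 rose (adjusted p = 0.13), each with most called members lower in SSEA1pos cells. In mean log2(CPM + 1) the keratinocyte list stood at 2.62, 3.39 and 1.59 in SSEA1neg replicates 1, 2 and 3 against 1.35 to 1.84 in SSEA1pos libraries, and the neural list at 4.25, 2.78 and 2.53 against 2.67 to 2.86. From day 12 to the iPS stage the muscle list had 3 of 11 rose and 0 fell, the 3 being Myog, Ttn and Cdh15 (adjusted p = 0.0068, adjusted p = 0.2 with an estimated correlation). The list of cell cycle inhibitors and p53 targets had 7 of 18 fell and 2 rose at the day 12 sort (adjusted p = 0.25). Genes of SSEA1 synthesis and of the sort-related surface went both ways, with 7 of 15 fell and 5 rose (8 fell adjusted over the list alone) at day 12 (adjusted p = 0.21) and 9 of 15 fell and 3 rose (4 rose adjusted over the list alone) at the iPS stage (adjusted p = 0.14). The unfolded protein and stress list of day 9 SSEA1neg cells against MEFs had 9 of 19 fell and 2 rose (adjusted p = 0.00027, adjusted p = 0.47 with an estimated correlation). Its members that rose, named after their values were seen, were Gclm (1.70 ± 0.28) and Nqo1 (1.65 ± 0.51), genes of the oxidative stress response, while Chac1, a target of ATF4, fell (-5.57 ± 0.85).

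The genes of this paragraph were picked after their values were seen, and some followed the replicate number in part of the groups. Meg3 stood at 84.8, 933 and 781 CPM in MEF replicates 1, 2 and 3, at 4.45, 274 and 357 in day 3 SSEA1pos cells and at 65.7, 909 and 906 in day 6 SSEA1pos cells, but at 390 CPM in day 6 SSEA1neg replicate 1. Xist was at 138, 226, 153 and 96.3 CPM in replicate 1 of the SSEA1pos groups of days 3, 6, 9 and 12. In replicate 1 of the SSEA1neg groups of these days it was at 428, 772, 806 and 738 CPM. Lyz2 stood at 1.34, 65.2 and 9.46 CPM in the MEF replicates and at 1.68, 396 and 3.61 in the iPS-stage SSEA1neg replicates. In that last group Igf2 was at 2550, 1910 and 191 CPM and H19 at 3710, 3610 and 295. Neither gene followed the number across groups. In day 12 SSEA1neg replicates 1, 2 and 3 Igf2 was at 2390, 2100 and 2700 CPM and H19 at 4880, 3970 and 4620.

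Genes of high GC content were lower in most SSEA1neg libraries. Their slope of log2 CPM per 10 GC points averaged -0.43 ± 0.37 at day 3, against -0.02 ± 0.12 in day 3 SSEA1pos cells and 0.2 ± 0.07 in MEFs. Of the 15 SSEA1neg libraries, 9 had a slope below all 18 other libraries, and 12 lay below them in genes of over 62% GC. Within a stage the SSEA1neg library had a lower slope than the same-numbered SSEA1pos library in 14 of 15 pairs (the exception was day 12 replicate 3, 0.29 against 0.23), and a lower median of the 161 genes of over 62% GC in 15 of 15, in 13 by more than the SD between SSEA1pos replicates (0.09). A GC content bias of the libraries, or loss of very GC-rich transcripts from every SSEA1neg library, thus stays open, as does a change of the cells that goes with the sort (the MEF mean slope of 0.2 lay nearer the day 3 SSEA1pos mean, but MEFs also differ in medium and doxycycline), and these cannot be told apart since the trend goes with the sort itself. GC as the whole of the day 12 difference was argued against by the 96.2% of its called genes that stayed called with a replicate block and the GC trend removed, and as the whole of the decreases at the day 3 sort by at least 67.7% under 3 settings without the GC trend. Of the increases at the day 3 sort 54.6% stayed called with the block and no GC trend, 49.6% without the GC trend and 36.2% without GC and length, so GC as their whole cause was not excluded.

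Replicate 3 of the iPS-stage SSEA1neg group held far more pluripotency RNA than replicates 1 and 2 (Nanog 441 against 21.4 and 59.5 CPM). Its median level of 107 genes specific to iPS-stage SSEA1pos cells was 0.42 of the SSEA1pos level (quartiles 0.3 to 0.55), and that of 407 genes specific to replicates 1 and 2 was 0.64 of their level (quartiles 0.36 to 1.11; 0.76 and 1.24 in replicates 1 and 2 themselves). An SSEA1pos library that carries the SSEA1neg label was argued against by the 0.64, as it needs at most 0.1. Both shares add up to 1.05, in line with a mix of both kinds of cells, which needed 0.7 to 1.3, but the spread of the second share is wide, and such a mix leaves open why Igf2 (191 against 2550 and 1910 CPM) and H19 (295 against 3710 and 3610 CPM) lay far below 0.64 of replicates 1 and 2 and the imprinted list within the SSEA1pos range. No biological explanation was tested, and cells between both states stay open.

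Xist fell in iPS-stage SSEA1pos libraries while X-linked genes rose relative to autosomal ones. The excess of the X-linked over the autosomal median log2 change from MEFs was 0.59 and met the value a second active X chromosome needs (at least 0.3), and on a hypothesis may reflect X reactivation. SSEA1neg cells of that stage had an excess of 0.35 too (0.25 with the GC trend removed). It was 0.28 and 0.44 in replicates 1 and 2, whose Xist was not low (547 and 921 CPM). These single-library values still hold the GC trend (slopes of -0.11 and -0.45). With that trend left in, an excess near or past 0.3 was thus also seen without a fall of Xist. Such an excess does not show reactivation by itself. Loss of the inactive X chromosome needs an excess within 0.1, and the excess was 0.59, or 0.55 with the GC trend removed. SSEA1neg replicates 1 and 2 also passed 0.1 with the GC trend left in, while their Xist was not low. Their group, replicate 3 included, had 0.25 with the trend removed, so that limit cannot decide. Such a loss thus stays open beside this excess. A GC content bias of the libraries was argued against as the whole of it, as 93% of the excess was left; the labels give no sex, and Xist in MEFs (224, 495 and 503 CPM) with no read in 4 Y-linked genes in any library is in line with female cells.

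Each comparison of 3 with 3 libraries has 10 splits, too few for a share under 0.05, and in each the real split alone (1 of 10) reached its own count. Refitted on the 6 libraries alone, the real splits of the sort called 1017, 2242, 4052, 5882 and 4402 genes from day 3 to the iPS stage. Those of SSEA1pos cells against MEFs called 4682, 4830, 5842, 7044 and 7712, those of SSEA1neg cells 4576, 4101, 4087, 4573 and 2745, and the steps between SSEA1pos stages 352, 43, 1252 and 1441. The highest other split called 0 genes in all of these but day 9 against day 6, where it called 1. Each other split mixed libraries of both real groups, so the difference between those groups entered the spread. Few calls would follow from that alone, and these counts do not exclude chance. Where replicate numbers paired the libraries, the real split parted all 3 pairs; the highest other split that did so called 0 genes, and the split with 1 gene parted 1 pair.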
